A study of Mus musculus with 12 samples.

How the data were processed

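The series holds 12 samples of mouse uterus from animals carrying a tamoxifen-inducible Cre driven by Pdgfra, a gene of fibroblasts, and a tdTomato reporter. Tissue was taken at embryonic day 18.5 of pregnancy (E18.5) and at postpartum day (PPD) 1, 2, 3, 4 and 28. Nuclei were isolated with a Singulator 100 and made into droplet libraries with the 10x Chromium 3 prime v3.1 kit. In 11 libraries a count matrix was available, with 2 replicates in each group except PPD1, which had 1, and PPD1 replicate 2 was not analysed here. Per the labels, the deposited matrices hold raw UMI counts per gene and barcode from Cell Ranger 7.0.1, with Seurat 5.1.0 and the mm10 build also named in the submitters' processing notes. Intron counting, the counting strand and the annotation release are not given in the sources used here. Each matrix lists 32286 features, 1 of them a tdTomato transcript. Coordinates were taken from GENCODE vM21 on GRCm38 by gene ID, which matched 32158 features.

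The total UMI count per library ranged from 28409770 to 76675092. Of 229247 barcodes, 228820 had at least 300 genes and at most 5% mitochondrial UMIs. They were normalised, reduced to 3000 variable genes, with 125 genes (mitochondrial genes, the reporter and the genes of the epithelial identity, mesenchymal identity, EMT, MET and cell cycle lists) barred from that set, and to 40 principal components, joined by 15 neighbours and grouped by the Leiden method at resolution 1 (scanpy 1.11.5, igraph 0.11.9). The 62 clusters were named from marker lists, with at least 3 markers raised. Cluster 16 had stromal markers but stayed unnamed for its leading genes. The 7 clusters with a median under 1200 UMIs held 120949 barcodes and are called low-UMI barcodes. They were left out of every class and used as the measure of RNA outside nuclei. Doublets were called per library with Scrublet in scanpy at an expected 0.8% per 1000 nuclei. A first run on all barcodes failed to find usable thresholds in several libraries, so doublets were taken from a second run without the low-UMI barcodes, a change made after the first run was seen. Clusters with over 50% called doublets, doublets in named clusters and unnamed clusters were also left out, and 97424 nuclei remained.

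For stroma, epithelium, smooth muscle and macrophages, the UMIs of the nuclei of each library with at least 20 such nuclei were summed. Sums were compared with edgeR 4.0.16 quasi-likelihood tests after TMM scaling and its filter on low counts. The fit had 1 coefficient per group, and the value of a side of a contrast was the mean of its groups' coefficients. The contrasts were PPD1-4 against E18.5, PPD1-4 against PPD28 and, in stroma and epithelium, PPD3-4 against PPD1-2. The PPD1-4 value weights the 4 days equally. PPD1 has 1 library and is assumed to vary like the other groups. Benjamini-Hochberg adjusted p under 0.05 counts as called, and "rose" and "fell" are used only for called genes. Levels are CPM, with the UMIs of a class scaled to the same total in each library, as mean ± SD over libraries. Numbers of nuclei per class were compared with the same tool with library totals as offsets, over 12 classes and the 3 contrasts together. The difference between stroma and epithelium was tested in a joint fit on library sums of both classes.

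The 24 gene lists were written before the data were examined, as were the groups, comparisons, thresholds, marker lists and the rule for named genes. The lists are epithelial identity, mesenchymal identity, epithelial-mesenchymal transition (EMT) transcription factors, regulators associated with mesenchymal-epithelial transition (MET), uterine gland, luminal epithelial, decidual, collagens, matrix proteases and inhibitors, inflammatory mediators, hypoxia and glycolysis, estrogen and progesterone response, Wnt target, TGF-beta and fibrosis response, cell cycle, interferon response, smooth muscle contractile, labour contraction-associated, immediate early and heat shock, autophagy with lysosome and apoptosis, macrophage resident and clearance, macrophage inflammatory and lipid, placental trophoblast, and blood genes. Each list was tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 24 lists of the comparison, and again with an estimated correlation, whose adjusted p follows that of the first as "estimated".

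Named genes were chosen by rule. In each comparison they are the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 5 and no overlap between the libraries of both sides. The gene's highest mean in any other class could be at most 4 times that of the higher side, and names of unannotated, mitochondrial and ribosomal genes were barred. Up to 3 called members of each discussed list with the smallest adjusted p were added, or the 2 with the highest expression where none was called. Of these, mainly genes whose call held with each library left out are named. A fixed set of identity genes was always included, being Pdgfra, Epcam, Cdh1, Krt8, Krt18, Vim, Col1a1, Col3a1, Zeb1, Zeb2, Grhl2, Esr1, Pgr and Mki67 in stroma and epithelium, Myh11, Acta2, Oxtr, Gja1, Esr1 and Pgr in smooth muscle, and Mrc1, C1qa, Ccr2 and Spp1 in macrophages. A fold against a group with 0 counts is a bound against a floor of 3 counts over the group.

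To compare nuclei at 1 depth, UMIs of nuclei with at least 1000 were thinned to 1000. A nucleus was scored positive for the epithelial identity list (25 genes) or for 12 mesenchymal genes at 2 or more UMIs, and as cycling at 3 or more UMIs of 40 cell cycle genes. The 12 mesenchymal genes are those of the list whose level in stroma was over 4 times that in endothelium. Vascular endothelial nuclei of the same library served as background. Shares carry exact Clopper-Pearson 95% intervals, which, like floors, cover counting error only. Shares were compared over libraries with exact permutation tests, of the one-way F over the 10395 ways to divide 11 libraries into the groups, for which the smallest p allowed is 9.62e-05, and two-sided of PPD1-4 against E18.5 with PPD28 over 330 splits, smallest p 0.00303. Classes with under 50 such nuclei in a library were not scored in it. Genes called in 1 direction in both PPD1-4 contrasts were counted as transient.

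The pipeline was tested on simulated data. Depending on the class, 5.00% to 43.0% of planted 2-fold changes and 49.0% to 89.0% of 4-fold changes were called, and up to 12.9% of calls were false. Alternatives were edgeR RLE size factors, DESeq2 1.42.0, no filter on low counts, doublets kept, at least 500 genes per nucleus, Leiden resolution 0.5, each library left out in turn, the replicate number as a block, thinning to 500 UMIs, other thresholds and background classes. Added after the data were seen were cluster 12 left out of the stroma, cluster 16 added to it, doublets of the first Scrublet run, and a split of the shared libraries. Of 10 batch dates, 9 hold 1 library and 1 both PPD28 libraries, so no comparison can be adjusted for date. Figures were drawn with matplotlib 3.10.9. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0 and R 4.3.3 were used.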

Results

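UMI counts were read from single uterine nuclei in 11 libraries of 6 time points around birth, with 2 libraries each at E18.5, PPD2, PPD3, PPD4 and PPD28 and 1 at PPD1. Replicates 1 and 2 held 73507414 and 76675092 UMIs at E18.5, 68621049 and 71919871 at PPD2, 39789321 and 55231765 at PPD3, 58680163 and 71395940 at PPD4, and 28409770 and 29606119 at PPD28, and the PPD1 library held 55495061. Each library gave 6028 to 11037 analysed nuclei with a median of 2560 to 5025 UMIs. Low-UMI barcodes were 52.9% of kept barcodes, and they were nearly absent at PPD28 (0.148% in replicate 2), so RNA outside nuclei was not measurable in that group. The series title concerns mesenchymal cells that turn into epithelium while the endometrium heals after birth, and PPD1-4 was compared with late pregnancy and with the rested uterus for that question. The labels do not say whether replicates are separate animals, so p-values measure only the spread between samples.

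Macrophages, which clear debris in healing tissue, made up 6.70% ± 0.00638 (SD, n = 2) of analysed nuclei at E18.5, 17.6% at PPD1, 8.78% ± 0.792 (n = 2) at PPD4 and 1.13% ± 0.733 (n = 2) at PPD28. Stromal fibroblasts went from 33.8% ± 1.79 (n = 2) at E18.5 to 16.1% at PPD1, stood at 40.6% ± 1.94 (n = 2) at PPD4 and at 4.24% ± 4.36 (n = 2) at PPD28. Epithelium, the lining and glands, held 35.1% ± 4.27 (n = 2), 12.2% ± 1.31 (n = 2) and 56.7% ± 1.66 (n = 2) at E18.5, PPD3 and PPD28. Mesothelium, the outer cover of the uterus, held 3.53% ± 1.63 (n = 2) at E18.5 and 14.4% ± 0.623 (n = 2) at PPD4. B and plasma cells stood at 1.95% ± 0.00394 (n = 2) at PPD4. Against PPD28, PPD1-4 had higher shares of macrophages (log2 ratio 3.51, adjusted p = 0.000213), B and plasma cells (adjusted p = 4.1e-05, with 1 nucleus in each PPD28 library), T cells (1.99, 0.00205), stroma (2.40, 0.00825), vascular endothelium (2.19, 0.00470), pericytes (2.82, 0.00302), dendritic cells (1.51, 0.00825) and lymphatic endothelium (1.18, 0.0353), and lower shares of epithelium (-1.68, 0.00205) and mesothelium (-1.2, 0.0148). Against E18.5, mesothelium (1.6, 0.00825), pericytes (1.32, 0.0454) and dendritic cells (1.07, 0.0345) were higher and epithelium was lower (-0.99, 0.0345). B and plasma cells were higher at PPD3-4 than at PPD1-2 (1.0, 0.0353). In all, 15 of 36 class tests passed, and 14 with cluster 16 added to the stroma. Exact permutation tests of F over times gave p = 0.000289 (adjusted over the 12 classes, 0.00346) for stroma and 0.00529 (0.0182) for macrophages. The mean of PPD1-4 lay above the mean of the E18.5 and PPD28 libraries by 8.83 percentage points for macrophages (two-sided exact permutation p = 0.00303, the smallest allowed) and by 6.32 for stroma (p = 0.473), although stroma at PPD1, PPD2 and PPD3 lay below E18.5. Mesothelium was no longer called against E18.5 without E18.5 replicate 2 (adjusted p = 0.0822) or against PPD28 without PPD28 replicate 2 (0.107), and epithelium against E18.5 was not called without either E18.5 library (0.0828 and 0.148), PPD3 replicate 2 (0.0671) or either PPD4 library (0.0553 and 0.0886). Pericytes against E18.5 lost the call without either E18.5, PPD2 or PPD4 library or PPD3 replicate 1 (0.0509 to 0.212), and dendritic cells without any E18.5, PPD3 or PPD4 library (0.0626 to 0.134). Lymphatic endothelium against PPD28 lost it without either E18.5 or PPD4 library, PPD1 or PPD28 replicate 2 (0.0549 to 0.117), and B and plasma cells within PPD1-4 without PPD2 replicate 1 or any PPD3 or PPD4 library (0.0509 to 0.123).

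**Figure D1:**
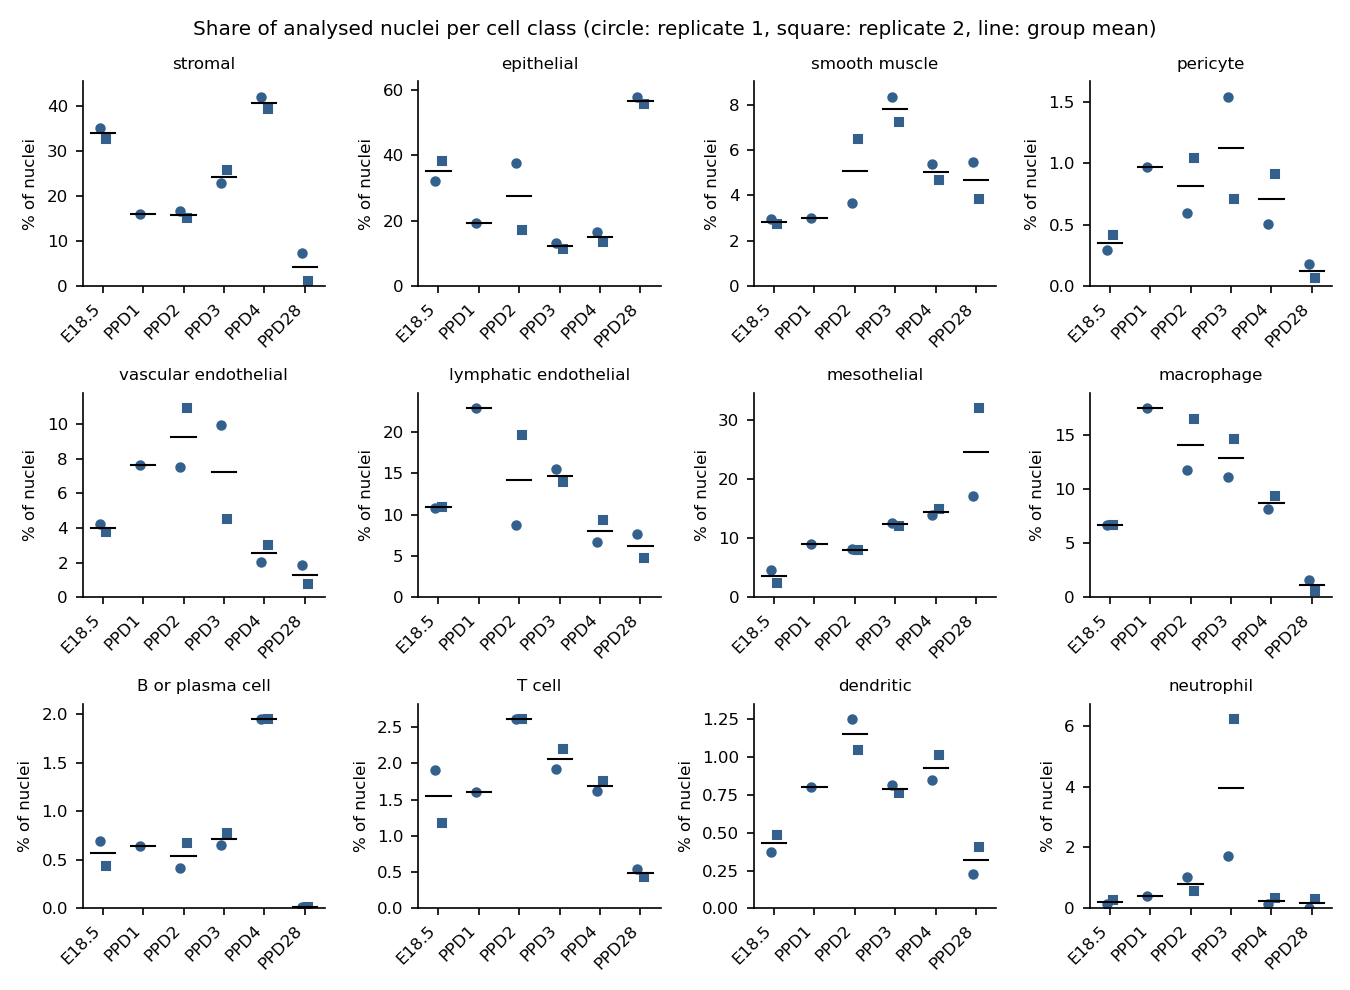
Share of analysed nuclei in percent (y axis) for each cell class by time point (x axis), with a point per library and a bar at the mean. Macrophages stood at 17.6% at PPD1 and 1.13% at PPD28, and stroma, without the unnamed cluster 16, at 16.1% and 4.24%.

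Clusters of stroma, epithelium and smooth muscle were split by time, so group and cluster overlap. Stromal cluster 12 held 71.1% and 67.3% of the stroma of both E18.5 libraries, cluster 7 held 57.3% to 81.3% in PPD3 and PPD4, cluster 21 held 96.3% at PPD1, and cluster 44 held 99.8% in PPD28 replicate 1, whereas cluster 13 held 80.7% in PPD28 replicate 2. Epithelial cluster 18 held 81.1% of PPD28 replicate 1 and cluster 17 held 92.0% of replicate 2. In smooth muscle cluster 38 held 99.1% and 100% of both E18.5 libraries and cluster 49 held 99.7% of PPD28 replicate 1, while cluster 15 held 99.3% of PPD28 replicate 2. Macrophage cluster 57 held 66.1% and 61.4% of the macrophages at PPD28. The PPD28 sides of the stromal and macrophage tests rest on few nuclei, 483 and 83 in stroma and 109 and 44 in macrophages.

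Stromal nuclei gained transcripts of Kif26b and Lef1 and lost those of Cyp11a1 and Olr1 between E18.5 and PPD1-4. Kif26b, for a kinesin-like protein of cell polarity (ENSMUSG00000026494, mm10 chromosome 1, 178529125 to 178939200), went from 3.1 ± 1.47 CPM (n = 2) to 676 ± 464 (n = 7), a log2 rise of 7.28 (adjusted p = 1.62e-05). Lef1, a transcription factor of Wnt signalling (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356), rose by 5.37 (3.73e-06), from 1.18 ± 0.446 (n = 2) to 140 ± 154 CPM (n = 7). The wound matrix gene Tnc rose by 5.64, the collagen gene Col26a1 by 5.45, and the membrane protein genes Tspan11 and Tmem132c by 6.16 and 5.59. Cyp11a1, for the enzyme that starts steroid synthesis (ENSMUSG00000032323, chromosome 9, 58006411 to 58027023), went from 400 ± 84.3 (n = 2) to 2.33 ± 3.60 CPM (n = 7), a change of -7.99 (7.63e-08), and the scavenger receptor gene Olr1 fell by 7.11. The decidual hormone gene Prl8a2 fell by 6.28, while Guca2b, Akr1c18 and Rbp4 fell by 10.15, 8.85 and 7.13. At E18.5 the stromal CPM of Cyp11a1 and Olr1 was 2.72 and 3.21 times that of the low-UMI barcodes, against 0.174 for Guca2b, 0.190 for Akr1c18, 0.715 for Prl8a2 and 0.869 for Rbp4. Counts of the near-identical Sprr2, Prl, Akr1c and globin genes are uncertain, as are those of antisense genes, because the strand that was counted is not given in the sources used here. Cluster 16, 3807 unnamed nuclei with stromal markers that lay almost wholly in PPD1-4 libraries, bears on these falls. With it added, as chosen after the data were seen, Cyp11a1 stood at -4.75 and Olr1 at -4.89. With cluster 12 left out they stood at -5.01 and -4.51, and Kif26b, Lef1, Tspan11 and Tmem132c at 6.31, 4.59, 4.84 and 4.01, all still called.

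Of 18057 genes tested in stroma, 6368 changed against E18.5, 2721 up and 3647 down. Among 15 measured Wnt target genes, 9 rose, 0 fell and 6 did not pass, Apcdd1 at 4.57 among them, and 10 passed when adjusted over the list alone (camera adjusted p = 7.03e-06, 0.185 with an estimated correlation). Their level in stroma was 1.16 times that in low-UMI barcodes as a median. Decidual genes, those of the stroma of pregnancy, had 1 rise and 10 falls among 18, Cryab at -4.32, and 11 passed adjusted over the list alone (adjusted p = 0.000877, 0.185 estimated). Of 25 epithelial identity genes 0 rose and 13 fell, with Krt18 at -2.25, and 15 passed adjusted over the list alone (0.00107, 0.901 estimated), at a median of 0.170 of the low-UMI level at E18.5. Of 9 measured EMT transcription factors 5 rose, among them Twist2 (1.75) and Snai1 (1.76), and 0 fell, with 5 adjusted over the list alone (0.0475, 0.693 estimated), and Zeb1 rose by 0.77. Trophoblast genes, which are placental, had 9 falls among 11 measured, all 9 also adjusted over the list alone, Tpbpa at -8.77, and held 0.470 of the low-UMI level at E18.5 (5.19e-06, 0.185 estimated). Labour genes had 9 rises and 4 falls among 20, with Itpr1 at 1.87, Cacna1c at 2.32 and Ptgs1 at -2.66, and 13 passed adjusted over the list alone (0.0243, 0.185 estimated). Autophagy and lysosome genes had 1 rise and 13 falls among 26, Ctsb at -2.16, and 15 passed adjusted over the list alone (0.0369, 0.191 estimated). Krt8 (-1.47), Epcam (-0.95) and the progesterone receptor gene Pgr (-0.93) fell, while Pdgfra (0.39), Cdh1 (-0.45), Vim (-0.19), Col1a1 (-0.91), Col3a1 (0.10), Zeb2 (0.10), Grhl2 (-0.80), Esr1 (0.43) and Mki67 (0.87) did not pass. Without E18.5 replicate 1 or 2, 2944 or 2934 genes changed. Epcam, Zeb1 and Pgr (adjusted p = 0.0330, 0.0354 and 0.0344) did not pass without E18.5 replicate 1 (0.0905, 0.291 and 0.144) or 2 (0.285, 0.144 and 0.191), Epcam also without either PPD3 or PPD4 library (0.0517 to 0.0674), Zeb1 without these or PPD2 replicate 2 (0.0513 to 0.0635), and Pgr without PPD1, PPD2 replicate 1, either PPD3 library or PPD4 replicate 1 (0.0530 to 0.0704), nor Krt8 without E18.5 replicate 2 (0.101). The EMT list was not called without E18.5 replicate 2 (0.0857), PPD1 (0.0816), PPD2 replicate 2 (0.0710), PPD3 replicate 1 (0.0604) or PPD4 replicate 2 (0.0704), nor autophagy genes without PPD2 replicate 2 (0.0710) or PPD3 replicate 1 (0.0504). With cluster 12 left out of the stroma, an alternative chosen after the data were seen, Zeb1 stood at -0.23 and Col3a1 at -1.29, and EMT, labour and autophagy genes were not called (0.301, 0.0869 and 0.153).

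Compared with the rested uterus at PPD28, stroma of PPD1-4 had more transcript of Tnc and Dkk2 and less of Col4a4 and Aldh1a1. Tnc (ENSMUSG00000028364, chromosome 4, 63959785 to 64047015) stood at 324 ± 242 CPM (n = 7) against 7.68 ± 1.69 (n = 2), a log2 rise of 4.87 (adjusted p = 0.00948). Dkk2, for a secreted Wnt regulator, rose by 5.33 and Lrrc7, for a synaptic scaffold protein, by 6.06. Masp1, a complement protease gene, had 0 counts at PPD28 and was at least 14.0-fold higher in PPD1-4 (27.1 ± 11.8 CPM, n = 7). Col4a4, for a basement membrane collagen (ENSMUSG00000067158, chromosome 1, 82448423 to 82586849), stood at 14.2 ± 3.78 (n = 7) against 142 ± 35.6 (n = 2), a change of -3.45 (8.66e-05). Falls also included Aldh1a1 of retinoic acid synthesis (-3.29) and Rtl4 (-5.48).

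In this comparison 2352 stromal genes changed, 1159 up and 1193 down. Epithelial identity genes fell in 14 of 25 and rose in 0, Pax8 at -2.89, and 16 passed adjusted over the list alone (camera adjusted p = 8.58e-06, 0.720 with an estimated correlation). MET regulators fell in 10 of 17 and rose in 1, with 13 passing adjusted over the list alone (0.000122, 0.613 estimated). Luminal genes fell in 4 of 11 and rose in 0, with 5 adjusted over the list alone (0.0149, 0.613 estimated), and cell cycle genes fell in 20 of 40 and rose in 0, with 26 adjusted over the list alone (0.0149, 0.912 estimated). Proteases and inhibitors had 6 rises and 1 fall among 26, Plau at -2.16, with 11 adjusted over the list alone (0.0152, 0.613 estimated). Macrophage lipid genes had 4 rises among 21, Fn1 at 1.56 and Lpl at 2.37 (0.00459, 0.613 estimated). Blood genes had 1 rise among 5 (0.0349, 0.613 estimated), with 5 and 2 adjusted over the list alone, and both lists lay at 0.297 and 0.202 of the low-UMI level in PPD1-4. Cdh1 (-2.49), Grhl2 (-2.99) and Epcam (-1.39) fell and Vim (1.18) rose, whereas Pdgfra (0.80), Krt8 (0.04), Krt18 (-0.24), Col1a1 (-0.42), Col3a1 (0.21), Zeb1 (-0.14), Zeb2 (-0.61), Esr1 (-0.06), Pgr (-0.80) and Mki67 (-1.22) did not pass. PPD28 replicate 1 decides much of this comparison: without it few of these calls held, and Epcam turned to 0.40 on the log2 scale. In that library 67.2% of stromal nuclei scored positive for epithelial genes, against 52.9% of endothelial nuclei. At Leiden resolution 0.5 Epcam turned too, to 0.71. Falls of epithelial and MET genes may thus not be stromal. Without PPD28 replicate 2, 3608 genes changed, and at Leiden resolution 0.5, 224. Without PPD1, Vim (0.159), luminal, protease, cell cycle and blood genes (0.0580) were not called, nor was Epcam without PPD3 replicate 1 (0.0536) or 2 (0.0607), luminal genes without PPD2 replicate 2 (0.0553), or blood genes without PPD2 replicate 1 (0.129) or 2 (0.110) or PPD28 replicate 2 (0.0744).

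Within the first days after birth, stroma at PPD3-4 had more transcript of Ankfn1 and Lef1 than at PPD1-2, and less of Sprr2f and Adgrd1. Ankfn1, for a protein of planar cell polarity (ENSMUSG00000047773, chromosome 11, 89390223 to 89777653), went from 8.22 ± 7.14 (n = 3) to 97.4 ± 40.1 CPM (n = 4), a log2 rise of 4.60 (adjusted p = 0.000164). The adhesion gene Cntn3 rose by 4.28, Col26a1 by 4.07 and Lef1 by 3.83. Sprr2f, a gene of the cornified envelope (ENSMUSG00000050635, chromosome 3, 92365187 to 92366442), went from 515 ± 63.0 (n = 3) to 24.5 ± 17.0 CPM (n = 4), a change of -4.63 (0.000428), and the antibody transporter gene Pigr fell by 3.61. The activin subunit gene Inhbb fell by 3.15 and the adhesion receptor gene Adgrd1 by 2.79. At PPD1-2 the stromal CPM of Adgrd1 was 6.76 times the low-UMI CPM, against 0.235 for Sprr2f, 0.290 for Pigr and 0.831 for Inhbb.

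In this comparison 1859 stromal genes changed, 779 up and 1080 down. Wnt target genes rose in 6 of 15 and fell in 0, Lef1 and Apcdd1 (2.35) among them, with 8 passing adjusted over the list alone (camera adjusted p = 8.96e-06, 0.152 with an estimated correlation). Cell cycle genes rose in 5 of 40 and fell in 0, with 14 adjusted over the list alone (8.63e-05, 0.596 estimated). Epithelial identity genes fell in 18 of 25 and rose in 0, Elf3 at -3.16, with 23 adjusted over the list alone (9.67e-12, 0.232 estimated), and lay at 0.257 of the low-UMI level at PPD1-2 and 0.182 at PPD3-4. MET regulators had 1 rise, Bmp7 at 2.76, and 7 falls among 17, with 11 adjusted over the list alone (0.00966, 0.503 estimated). Inflammatory mediators fell in 8 of 25 and rose in 0, Lcn2 at -5.11, with 8 adjusted over the list alone (4.48e-05, 0.223 estimated). Interferon genes fell in 10 of 22 and rose in 0, with 17 adjusted over the list alone (1.29e-08, 0.223 estimated). Immediate early and heat shock genes fell in 9 of 23 and rose in 0, with 15 adjusted over the list alone (1.03e-05, 0.232 estimated). Hypoxia and glycolysis genes fell in 10 of 24 and rose in 0, with 16 adjusted over the list alone (4.48e-05, 0.320 estimated). Autophagy and lysosome genes fell in 7 of 26 and rose in 0, with 9 adjusted over the list alone (1.09e-06, 0.0606 estimated). Proteases and inhibitors had 1 rise and 8 falls among 26, Mmp7 at -4.02, with 15 adjusted over the list alone (8.63e-05, 0.178 estimated). Collagens and their enzymes had 1 rise, Col18a1 at 1.25, and 3 falls among 26, Lox at -2.33, with 4 adjusted over the list alone (0.0293, 0.663 estimated). TGF-beta response genes fell in 5 of 18 and rose in 0, with 7 adjusted over the list alone (0.0184, 0.223 estimated). Macrophage resident genes had 1 rise and 10 falls among 15 (3.39e-05, 0.223 estimated). Macrophage lipid genes had 10 falls among 21 (2.42e-05, 0.223 estimated), with 12 and 13 adjusted over the list alone, at 0.320 and 0.339 of the low-UMI level at PPD1-2. Epcam (-1.61), Cdh1 (-1.30), Krt8 (-1.70), Krt18 (-1.55) and Vim (-1.51) fell, while Pdgfra (-0.48), Col1a1 (-0.17), Col3a1 (-0.03), Zeb1 (0.75), Zeb2 (0.30), Grhl2 (-1.27), Esr1 (0.83), Pgr (0.65) and Mki67 (1.33) did not pass. Without E18.5 replicate 1 or 2 the count was 1181 or 1163, and without PPD3 replicate 1 or 2, 808 or 1182. It was 1065 or 1144 without PPD4 replicate 1 or 2, 3068 or 3071 without PPD28 replicate 1 or 2, 3076 with no filter on low counts, and at Leiden resolution 0.5, 3525. Vim was not called without PPD1 (0.131), Epcam (0.0567) and Krt8 (0.0614) without PPD3 replicate 1, and Cdh1 without any library other than PPD1 or PPD28 (0.0530 to 0.153). Of the lists, Wnt targets lost the call without PPD1 (0.0502), collagens without PPD1 (0.988), PPD2 replicate 2 (0.276) or PPD4 replicate 1 (0.0597), and TGF-beta genes without PPD2 replicate 2 (0.0937) or PPD4 replicate 1 (0.0620).

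**Figure D2:**
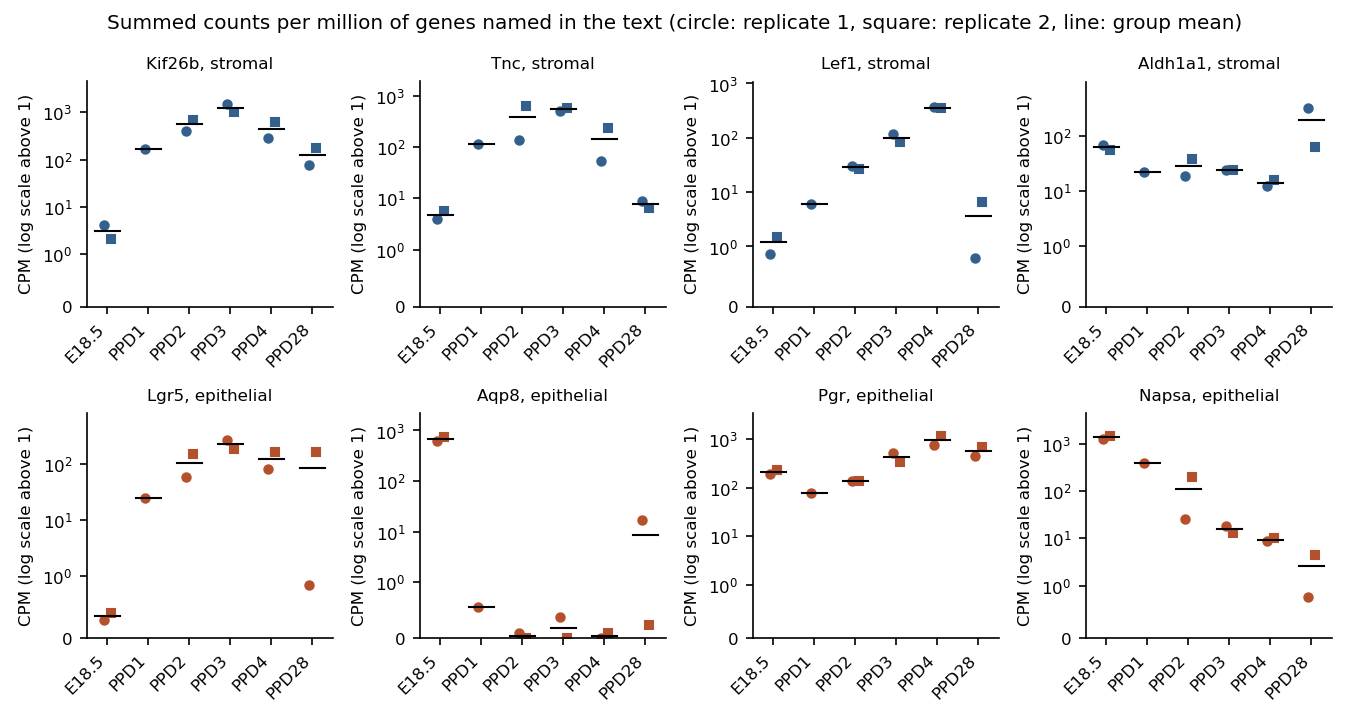
CPM of 8 named genes in stroma (upper panels) or epithelium (lower panels) (y axis, log scale above 1) by time point (x axis), 1 symbol per library and a line at the group mean. Stromal Kif26b averaged 3.1 CPM at E18.5 and 676 over PPD1-4, and epithelial Aqp8 averaged 676 at E18.5 and 0.160 over PPD1-4.

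Epithelial nuclei gained transcripts of Ntf3 and Kif26b and lost those of Aqp8, Kcne2 and Abcb1b between E18.5 and PPD1-4. Ntf3, for a neurotrophin (ENSMUSG00000049107, chromosome 6, 126101412 to 126166910), went from 0.933 ± 0.266 (n = 2) to 145 ± 111 CPM (n = 7), a log2 rise of 6.70 (adjusted p = 0.00161). Lgr5, the R-spondin receptor gene of epithelial stem cells, rose by 7.97 and Kif26b by 7.05. The water channel gene Aqp8 (ENSMUSG00000030762, chromosome 7, 123462291 to 123468004) went from 676 ± 88.0 (n = 2) to 0.160 ± 0.218 CPM (n = 7), a change of -12.18 (0.000190). The potassium channel gene Kcne2 fell by 10.71, Guca2b by 9.66, the progesterone-degrading enzyme gene Akr1c18 by 9.31 and Cuzd1 by 9.22. Abcb1b, for an efflux transporter, fell by 9.19 from 16387 ± 2095 (n = 2) to 38.3 ± 47.7 CPM (n = 7). Relative to low-UMI barcodes at E18.5, epithelial CPM was 3.18 for Abcb1b, 1.26 for Kcne2, 0.826 for Aqp8, 0.734 for Cuzd1, 0.618 for Guca2b and 0.606 for Akr1c18.

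Of 19536 genes tested in epithelium, 5836 changed against E18.5, 2365 up and 3471 down. Wnt target genes had 11 rises and 1 fall among 15, Lef1 at 4.89, Rnf43 at 2.33 and Dkk2 at 2.16, with 14 adjusted over the list alone (camera adjusted p = 3.65e-05, 0.656 with an estimated correlation), and went from 0.508 to 1.24 of the low-UMI level. Cell cycle genes had 5 rises and 1 fall among 40, with 2 adjusted over the list alone (0.0171, 0.904 estimated). Interferon genes had 8 rises and 1 fall among 22, Bst2 at -2.27, with 10 adjusted over the list alone (0.0320, 0.822 estimated). EMT transcription factors rose in 3 of 9 and fell in 0, Zeb1 (1.17) among them, with 5 adjusted over the list alone (0.0343, 0.814 estimated), and held 0.143 of the low-UMI level. Decidual genes fell in 8 of 17 and rose in 0, Cryab at -5.31, with 8 adjusted over the list alone (0.0488, 0.656 estimated), at 0.255 of the low-UMI level at E18.5. Trophoblast genes had 1 rise, Gata2 at 2.35, and 5 falls among 10, Tpbpa at -9.60, with 6 adjusted over the list alone (0.0320, 0.656 estimated), at 0.187 of that level. Krt8 (-1.23) and Krt18 (-2.17) fell, whereas Pdgfra (0.52), Epcam (-0.11), Cdh1 (0.57), Vim (-0.06), Col1a1 (-0.81), Col3a1 (-0.16), Zeb2 (1.19), Grhl2 (-0.18), Esr1 (-0.24), Pgr (0.26) and Mki67 (1.52) did not pass. Without E18.5 replicate 1 or 2, 2542 or 2011 genes changed and the calls of Lgr5 (0.105, 0.121) and Zeb1 (0.246, 0.196) were lost. Krt8 was lost without E18.5 replicate 2 (0.246) and Zeb1 also without PPD2 replicate 1 (0.0511) or 2 (0.0722) or PPD4 replicate 2 (0.0732). Wnt and cell cycle genes kept the list call without each library. Without PPD28 replicate 1 or 2, EMT, interferon and trophoblast genes were at 0.0603 or 0.0601 and decidual genes at 0.0661 or 0.0659. Without PPD1 EMT was at 0.0682 and interferon at 0.107, and without E18.5 replicate 2 interferon was at 0.0672. Decidual genes were at 0.0504 to 0.0599 without E18.5 replicate 1, either PPD2 or PPD4 library or PPD3 replicate 1.

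Against PPD28, epithelium of PPD1-4 had more transcript of Slc24a5 and Adamts16 and less of Sema3a and Dhrs9. Slc24a5, for an ion exchanger (ENSMUSG00000035183, chromosome 2, 125068124 to 125088677), stood at 42.4 ± 19.5 CPM (n = 7) against 3.47 ± 1.10 (n = 2), a log2 rise of 3.58 (adjusted p = 0.00869). The matrix protease gene Adamts16 rose by 3.25. Sema3a, an axon guidance gene (ENSMUSG00000028883, chromosome 5, 13125414 to 13602565), stood at 88.1 ± 44.7 (n = 7) against 765 ± 257 CPM (n = 2), a change of -3.48 (0.00627). The retinol dehydrogenase gene Dhrs9 fell by 4.67. In PPD1-4, the CPM of Slc24a5 and Adamts16 in epithelium was 4.21 and 7.12 times the low-UMI CPM.

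This comparison changed 4153 epithelial genes, 1947 up and 2206 down. Proteases and inhibitors rose in 12 of 27 and fell in 0, Mmp2 at 2.81, with 16 adjusted over the list alone (camera adjusted p = 1.89e-05, 0.371 with an estimated correlation). Macrophage lipid genes had 11 rises and 1 fall among 22, with 15 adjusted over the list alone (2.01e-05, 0.371 estimated). Macrophage resident genes had 11 rises and 1 fall among 18, with 15 adjusted over the list alone (0.000133, 0.471 estimated). Blood genes rose in 4 of 6 and fell in 0, with 5 adjusted over the list alone (0.00590, 0.508 estimated). These 4 lists lay at 0.229, 0.198, 0.172 and 0.152 of the low-UMI level in PPD1-4. Mesenchymal identity genes rose in 8 of 25 and fell in 0, Pdgfra (2.09), Vim (2.12) and Thy1 (1.67) among them, with 8 adjusted over the list alone (0.0149, 0.642 estimated). Collagens rose in 6 of 26 and fell in 0, with 6 adjusted over the list alone (0.0196, 0.642 estimated). Both lists lay at 0.146 and 0.154 of the low-UMI level. EMT factors rose in 2 of 9 and fell in 0, Snai1 at 3.07, with 2 adjusted over the list alone (0.0310, 0.563 estimated), at 0.143 of that level. TGF-beta genes rose in 5 of 18 and fell in 0, Inhba at 3.48, with 6 adjusted over the list alone (0.0367, 0.508 estimated). Inflammatory mediators had 8 rises and 2 falls among 28, with 12 adjusted over the list alone (0.0367, 0.564 estimated). Autophagy genes had 7 rises and 1 fall among 26, with 11 adjusted over the list alone (0.0241, 0.371 estimated). Decidual genes had 6 rises and 3 falls among 17, with 10 adjusted over the list alone (0.0480, 0.371 estimated). MET regulators fell in 6 of 18 and rose in 0, with 8 adjusted over the list alone (0.0241, 0.471 estimated). Cell cycle genes fell in 4 of 40 and rose in 0, with 0 adjusted over the list alone (0.0241, 0.781 estimated). Interferon genes had 1 rise and 4 falls among 22, with 6 adjusted over the list alone (0.0496, 0.754 estimated). Grhl2 (-0.63), Esr1 (-0.86) and Pgr (-1.14) fell, whereas Epcam (0.59), Cdh1 (-0.63), Krt8 (0.89), Krt18 (0.36), Col1a1 (-0.42), Col3a1 (0.98), Zeb1 (0.23), Zeb2 (1.30) and Mki67 (-0.98) did not pass. The count was 1374 without PPD28 replicate 1, 7000 without replicate 2, 1974 or 1960 without E18.5 replicate 1 or 2, and 2299, 1951 or 2219 without PPD2 replicate 2, PPD3 replicate 2 or PPD4 replicate 1. Without PPD28 replicate 1, MET (0.0553) and inflammatory genes (0.0508) lost the call, Col1a1 stood at 2.67 (0.0174) and Mki67 at 3.72 (0.0305), and cell cycle genes turned upward (2.30e-07). Without PPD28 replicate 2, mesenchymal (0.887), EMT (0.640), MET (0.0637), decidual (0.517), inflammatory (0.133), TGF-beta (0.510), interferon (0.602) and autophagy genes (0.0744) lost the call, as did Pgr (0.0535), and collagens turned (0.965). With 1 library left out, Grhl2 and Esr1 were called only without PPD2 replicate 1, PPD3 replicate 1 or PPD28 replicate 2 (0.0592 to 0.237 otherwise). Other calls were lost without PPD1 for Pgr (0.159), decidual (0.133), cell cycle (0.232) and autophagy genes (0.0666), and without PPD4 replicate 2 for decidual (0.0504), inflammatory (0.0605) and interferon genes (0.127). They were lost without PPD2 replicate 1 for inflammatory genes (0.0554), without PPD3 replicate 2 for interferon genes (0.0671), and without E18.5 replicate 1 or 2 for decidual (0.0523, 0.0520) and interferon genes (0.0611, 0.0611).

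Between PPD1-2 and PPD3-4 the epithelium gained transcripts of Grin2b and Pgr and lost those of Kap and Tnip3. Grin2b, for a glutamate receptor subunit (ENSMUSG00000030209, chromosome 6, 135713233 to 136173511), went from 3.68 ± 1.34 (n = 3) to 151 ± 143 CPM (n = 4), a log2 rise of 4.76 (adjusted p = 0.00635). The sialic acid lyase gene Npl rose by 4.36. Kap, an androgen-regulated gene first known from kidney (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762), went from 683 ± 899 (n = 3) to 3.41 ± 3.77 CPM (n = 4), a change of -9.01 (0.00203). Akr1c18 fell by 5.42 and Tnip3, which restrains NF-kappaB, by 5.03. At PPD1-2 the epithelial CPM was 1.49 times the low-UMI CPM for Kap, 0.738 for Akr1c18 and 2.81 for Tnip3. Pgr rose by 2.65 (0.00408), from 117 ± 35.2 (n = 3) to 694 ± 356 CPM (n = 4).

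At this step 1787 epithelial genes changed, 809 up and 978 down. Cell cycle genes rose in 4 of 40 and fell in 0, with 35 adjusted over the list alone (camera adjusted p = 6.13e-11, 0.401 with an estimated correlation). Wnt target genes rose in 4 of 15 and fell in 0, Dkk2 at 2.38, with 8 adjusted over the list alone (5.39e-05, 0.391 estimated). Luminal genes had 2 rises, Msx1 at 2.37 among them, and 2 falls among 13, with 9 adjusted over the list alone (0.0310, 0.391 estimated). Epithelial identity genes fell in 12 of 25 and rose in 0, with 18 adjusted over the list alone (1.07e-05, 0.391 estimated). Autophagy and lysosome genes fell in 7 of 26 and rose in 0, with 13 adjusted over the list alone (5.99e-05, 0.180 estimated). Hypoxia and glycolysis genes had 1 rise and 7 falls among 24, with 10 adjusted over the list alone (0.00205, 0.391 estimated). Interferon genes fell in 2 of 22 and rose in 0, with 6 adjusted over the list alone (0.000539, 0.391 estimated). Immediate early and heat shock genes fell in 6 of 23 and rose in 0, with 8 adjusted over the list alone (0.00168, 0.391 estimated). Proteases and inhibitors fell in 4 of 27 and rose in 0, with 7 adjusted over the list alone (0.00830, 0.391 estimated). TGF-beta genes had 1 rise and 4 falls among 18, with 6 adjusted over the list alone (0.00861, 0.391 estimated). Inflammatory mediators had 1 rise and 4 falls among 28, with 6 adjusted over the list alone (0.0489, 0.438 estimated). Macrophage lipid genes fell in 9 of 22 and rose in 0, with 11 adjusted over the list alone (5.99e-05, 0.391 estimated). Macrophage resident genes had 2 rises and 7 falls among 18, with 15 adjusted over the list alone (0.000453, 0.391 estimated). Both lists lay at 0.226 and 0.179 of the low-UMI level at PPD1-2. Epcam (-0.88), Krt8 (-1.69), Krt18 (-1.13) and Vim (-1.27) fell, whereas Pdgfra (-0.10), Cdh1 (-0.39), Col1a1 (0.31), Col3a1 (0.29), Zeb1 (0.17), Zeb2 (-0.43), Grhl2 (-0.07), Esr1 (0.00) and Mki67 (3.64) did not pass. The count moved to 998 without either E18.5 library, 640 without PPD1, 829 or 1094 without PPD2 replicate 1 or 2, and 581 or 664 without PPD3 replicate 1 or 2. It was 925 or 810 without PPD4 replicate 1 or 2, and 4067 or 4038 without PPD28 replicate 1 or 2. It was 2935 with no filter on low counts, 2968 with DESeq2 and 805 with the doublets of the first Scrublet run left out, an alternative chosen after the data were seen. Apart from the PPD28 libraries, Epcam (0.0677 to 0.541) and Krt18 (0.0563 to 0.261) held only without PPD2 replicate 1, and Vim (0.0701 to 0.581) only without PPD3 replicate 2. Krt8 lost the call without PPD1 (0.224), PPD3 replicate 1 (0.0707) or PPD4 replicate 2 (0.0653). Among lists, luminal genes were lost without PPD1 (0.171), PPD3 replicate 1 (0.0812) or PPD4 replicate 1 (0.103), proteases without PPD3 replicate 1 (0.0586), immediate early genes without PPD1 (0.0843), and inflammatory genes without either E18.5 library (0.0535 each), PPD2 replicate 1 (0.169), PPD3 replicate 1 (0.119) or PPD4 replicate 1 (0.147).

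Smooth muscle nuclei had less transcript of 14 of 20 contractile genes in PPD1-4 than at E18.5. Des, for the muscle filament desmin, fell by 3.21, the tropomyosin gene Tpm2 by 4.46, Tagln by 3.52, the myosin gene Myh11 by 1.82 (adjusted p = 0.000735), the actin gene Acta2 by 2.20 and the oxytocin receptor gene Oxtr by 2.33. Ano4, for a lipid scramblase (ENSMUSG00000035189, chromosome 10, 88948994 to 89344762), went from 6.43 ± 3.81 (n = 2) to 576 ± 169 CPM (n = 7), a log2 rise of 6.42 (4.11e-05). Npr3, for the natriuretic peptide clearance receptor, had 0 counts at E18.5 and was at least 278-fold higher at 355 ± 185 CPM (n = 7). Kif26b rose by 5.1. Guca2b (-11.52), Aqp8 (-10.88), Akr1c18 (-10.11), Rbp4 (-7.78) and Prap1 (-7.35) fell, at 0.287, 0.315, 0.342, 0.501 and 0.286 of the low-UMI CPM at E18.5. There Guca2b (ENSMUSG00000032978, chromosome 4, 119656607 to 119658954) stood at 1251 ± 356 (n = 2) against 0.845 ± 1.2 CPM (n = 7).

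Of 13940 genes tested in smooth muscle, 4644 changed against E18.5, 1844 up and 2800 down. Contractile genes fell in 14 of 20 and rose in 0, with 15 adjusted over the list alone (camera adjusted p = 5.97e-07, 0.241 with an estimated correlation), and went from 10.6 to 3.41 times the low-UMI level. Collagens fell in 16 of 26 and rose in 0, with 17 adjusted over the list alone (0.000146, 0.540 estimated). TGF-beta genes had 1 rise and 10 falls among 18, Tgfb2 at -3.49, with 13 adjusted over the list alone (0.0370, 0.241 estimated). Immediate early and heat shock genes fell in 13 of 19 and rose in 0, Hspb1 at -4.54, with 14 adjusted over the list alone (0.000106, 0.241 estimated). Decidual genes had 1 rise and 9 falls among 14, Cryab at -4.17, with 11 adjusted over the list alone (0.00170, 0.241 estimated). Epithelial identity genes fell in 21 of 25 and rose in 0, Wfdc2 at -3.60, with 21 adjusted over the list alone (3.53e-07, 0.415 estimated). MET regulators fell in 9 of 13 and rose in 0, with 9 adjusted over the list alone (0.00992, 0.540 estimated). Trophoblast genes fell in 4 of 5, Tpbpa at -7.81 (0.000829, 0.241 estimated). Blood genes fell in 5 of 5, Hbb-bs at -2.87 (0.0156, 0.504 estimated), with 4 and 5 adjusted over the list alone. The last 4 lists lay at 0.329, 0.489, 0.341 and 0.292 of the low-UMI level at E18.5. Gja1 (-0.51), Esr1 (0.00) and Pgr (-0.66) did not pass. Without E18.5 replicate 1 or 2, 2291 or 2206 genes changed and Oxtr was not called (0.0588, 0.0551), and MET regulators lost the call without E18.5 replicate 2 (0.357) or PPD28 replicate 2 (0.0504).

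Smooth muscle of PPD1-4 had more transcript of Gpnmb and Mmp11 than that of PPD28, and less of Kcnip4 and Dpp6. Serpine2, for a protease inhibitor (ENSMUSG00000026249, chromosome 1, 79794197 to 79861180), stood at 121 ± 39.0 CPM (n = 7) against 5.89 ± 0.147 (n = 2), a log2 rise of 4.33 (adjusted p = 0.000871). Ctla2a rose by 6.34, the lysosomal membrane gene Gpnmb by 4.65, Gpx3 by 4.21 and the matrix protease gene Mmp11 by 4.17. Kcnip4, for a potassium channel partner (ENSMUSG00000029088, chromosome 5, 48389502 to 49524907), stood at 203 ± 61.6 (n = 7) against 3115 ± 2485 CPM (n = 2), a change of -3.98 (0.000336). Dpp6, another channel partner gene, fell by 3.61. In PPD1-4, the smooth muscle CPM of Gpx3 was 0.257 of the low-UMI CPM, Serpine2 0.651, Ctla2a 0.916, Mmp11 1.17 and Gpnmb 1.80.

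Here 2514 smooth muscle genes changed, 1239 up and 1275 down. Proteases and inhibitors had 13 rises and 1 fall among 25, Mmp2 at 2.55, with 17 adjusted over the list alone (camera adjusted p = 7.19e-06, 0.0666 with an estimated correlation). Autophagy and lysosome genes had 11 rises and 1 fall among 26, with 13 adjusted over the list alone (0.00175, 0.243 estimated). Macrophage lipid genes rose in 8 of 18 and fell in 0, with 9 adjusted over the list alone (7.19e-06, 0.243 estimated). Macrophage resident genes had 9 rises and 1 fall among 15, with 11 adjusted over the list alone (0.000153, 0.285 estimated). These 4 lists lay at 0.465, 0.447, 0.285 and 0.408 of the low-UMI level. Blood genes rose in 3 of 5 and fell in 0, with 3 adjusted over the list alone (0.00198, 0.285 estimated). Decidual genes had 4 rises and 1 fall among 14, with 10 adjusted over the list alone (0.0200, 0.285 estimated). Epithelial identity genes fell in 12 of 25 and rose in 0, Grhl2 at -2.94, with 15 adjusted over the list alone (7.19e-06, 0.319 estimated). MET regulators fell in 9 of 13 and rose in 0, Ovol2 at -4.59, with 10 adjusted over the list alone (1.04e-05, 0.285 estimated). Luminal genes fell in 5 of 8 and rose in 0, with 5 adjusted over the list alone (0.00484, 0.285 estimated). Cell cycle genes fell in 14 of 37 and rose in 0, with 17 adjusted over the list alone (0.00164, 0.75 estimated). Oxtr (-2.28), Esr1 (-1.18) and Pgr (-1.23) fell, whereas Myh11 (-0.58), Acta2 (-0.19) and Gja1 (0.71) did not pass. Without PPD28 replicate 1, 534 genes changed, Oxtr (1.0), Pgr (0.700) and Esr1 (0.193) lost the call and cell cycle genes turned (0.349). The count was 1641 without PPD3 replicate 2, and Esr1 was not called without PPD1 (0.0665). Neither were luminal genes without PPD28 replicate 2 (0.0820), or decidual genes without PPD28 replicate 2 (0.541), E18.5 replicate 1 (0.0795) or PPD2 replicate 1 (0.0699).

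Macrophages of PPD1-4 had less transcript of Folr2 and Lyve1 than at E18.5 and more of Mdk, and none of the 3 passed at Leiden resolution 0.5 (adjusted p = 0.861, 0.486 and 0.0799). Folr2 fell by 2.35, Lyve1 by 2.74, the mannose receptor gene Mrc1 by 1.32, the complement gene C1qa by 1.25 and Spp1 by 1.32. Mdk, for the growth factor midkine (ENSMUSG00000027239, chromosome 2, 91929805 to 91932297), went from 5.90 ± 0.362 (n = 2) to 64.6 ± 21.6 CPM (n = 7), a log2 rise of 3.35 (adjusted p = 6.59e-06), at 0.336 of the low-UMI CPM. The cholesterol exporter gene Abcg1 rose by 1.81, at 5.39 times the low-UMI CPM. Aqp8 (-11.26), Guca2b (-9.84), Akr1c18 (-9.63), Cuzd1 (-9.61), Prap1 (-6.89) and Kap (-6.87) fell, at 0.337, 0.325, 0.359, 0.290, 0.311 and 0.333 of the low-UMI CPM at E18.5, where Aqp8 stood at 244 ± 31.2 (n = 2) against 0.0827 ± 0.219 CPM (n = 7).

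Of 15201 genes tested in macrophages, 1811 changed against E18.5, 480 up and 1331 down. Resident and clearance genes had 2 rises and 10 falls among 18, with 15 adjusted over the list alone (camera adjusted p = 0.0120, 0.536 with an estimated correlation), and went from 7.46 to 2.49 times the low-UMI level. Cell cycle genes fell in 3 of 40 and rose in 0, with 1 adjusted over the list alone (0.00131, 0.80 estimated). Immediate early and heat shock genes had 1 rise and 5 falls among 20, with 11 adjusted over the list alone (0.0307, 0.666 estimated). Epithelial identity genes fell in 11 of 25 and rose in 0, Wfdc2 at -2.82, with 13 adjusted over the list alone (8.13e-06, 0.582 estimated). Decidual genes fell in 6 of 15 and rose in 0, Cryab at -4.64, with 8 adjusted over the list alone (0.00131, 0.197 estimated). Trophoblast genes had 1 rise and 5 falls among 9, Tpbpa at -9.25, with 8 adjusted over the list alone (1.57e-06, 0.197 estimated). Blood genes fell in 3 of 6 and rose in 0, with 4 adjusted over the list alone (0.0120, 0.536 estimated). These 4 lists lay at 0.323, 0.449, 0.725 and 0.356 of the low-UMI level at E18.5. Wnt targets rose in 3 of 13 and fell in 0, with 8 adjusted over the list alone (0.0143, 0.536 estimated). Luminal genes rose in 1 of 8, Msx1 at 2.67, with 4 adjusted over the list alone (0.0366, 0.431 estimated). EMT factors were called as a list with 0 of 9 passing either way (0.0366, 0.536 estimated). The last 3 lists lay at 0.328, 0.316 and 0.346 of the low-UMI level in PPD1-4. Ccr2 (-0.66) did not pass. The count was 520 or 402 without E18.5 replicate 1 or 2, 2824 with no filter on low counts and 286 at Leiden resolution 0.5. There decidual genes alone of the 10 lists were still called, resident genes were at 0.833, and Mrc1 (0.53) and Lyve1 (1.89) turned upward without passing. Calls lost without E18.5 replicate 1 or 2 were those of Abcg1 (0.0590, 0.0991), C1qa (0.283, 0.123), Spp1 (0.552, 0.0509) and EMT genes (0.0636, 0.0561). Wnt genes were lost without replicate 1 (0.0700), and Mrc1 (0.217), immediate early (0.274), resident (0.0704), blood (0.0704) and luminal genes (0.0561) without replicate 2. Other losses were C1qa without PPD3 replicate 2 (0.0543) or PPD4 replicate 2 (0.0560), Spp1 without PPD3 replicate 1 (0.0643), luminal genes without PPD28 replicate 1 or 2 (0.0816, 0.0833), and EMT genes without PPD2 replicate 2 (0.0648), PPD3 replicate 2 (0.0612) or PPD4 replicate 2 (0.0504).

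Against PPD28, macrophages of PPD1-4 had far less of Timd4, a receptor gene of long-lived tissue macrophages. Timd4 (ENSMUSG00000055546, chromosome 11, 46810800 to 46844332) stood at 2.39 ± 2.36 CPM (n = 7) against 369 ± 113 (n = 2), a log2 change of -7.44 (adjusted p = 2.84e-06). The acute phase gene Saa3 fell by 7.68, the B cell attractant gene Cxcl13 by 7.33, the lubricant gene Prg4 by 7.09, the calcium channel gene Ryr2 by 7.0 and the coagulation factor gene F5 by 6.13. Of 9 genes known from macrophages of the peritoneal cavity, 9 fell too, Gata6 by 3.39 and Alox15 by 5.27 among them. C1qa fell by 1.74, while Mrc1 (1.38) and Spp1 (2.60) rose and Ccr2 (1.12) did not pass.

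In macrophages, 1944 genes changed against PPD28, 1015 up and 929 down. Mesenchymal identity genes had 8 rises and 1 fall among 25, Col3a1 at 2.20 and Fn1 at -4.16, with 16 adjusted over the list alone (camera adjusted p = 0.000835, 0.708 with an estimated correlation). Collagens rose in 10 of 25 and fell in 0, Col4a1 at 2.84, with 14 adjusted over the list alone (0.000835, 0.708 estimated). Proteases and inhibitors had 5 rises and 1 fall among 26, Mmp2 at 4.45, with 11 adjusted over the list alone (0.00421, 0.708 estimated). Contractile genes rose in 4 of 19 and fell in 0, with 5 adjusted over the list alone (0.0296, 0.734 estimated). The 4 lists lay at 0.332, 0.349, 0.373 and 0.351 of the low-UMI level in PPD1-4. Without PPD28 replicate 1, 551 genes changed and C1qa (0.264), Spp1 (0.0961), Mrc1 (0.220) and Col4a1 (0.0860) lost the call. Spp1 (0.108), Mrc1 (0.109), collagens (0.0586) and contractile genes (0.509) did so without PPD28 replicate 2, and Mrc1 without PPD1 (0.0521).

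**Figure D3:**
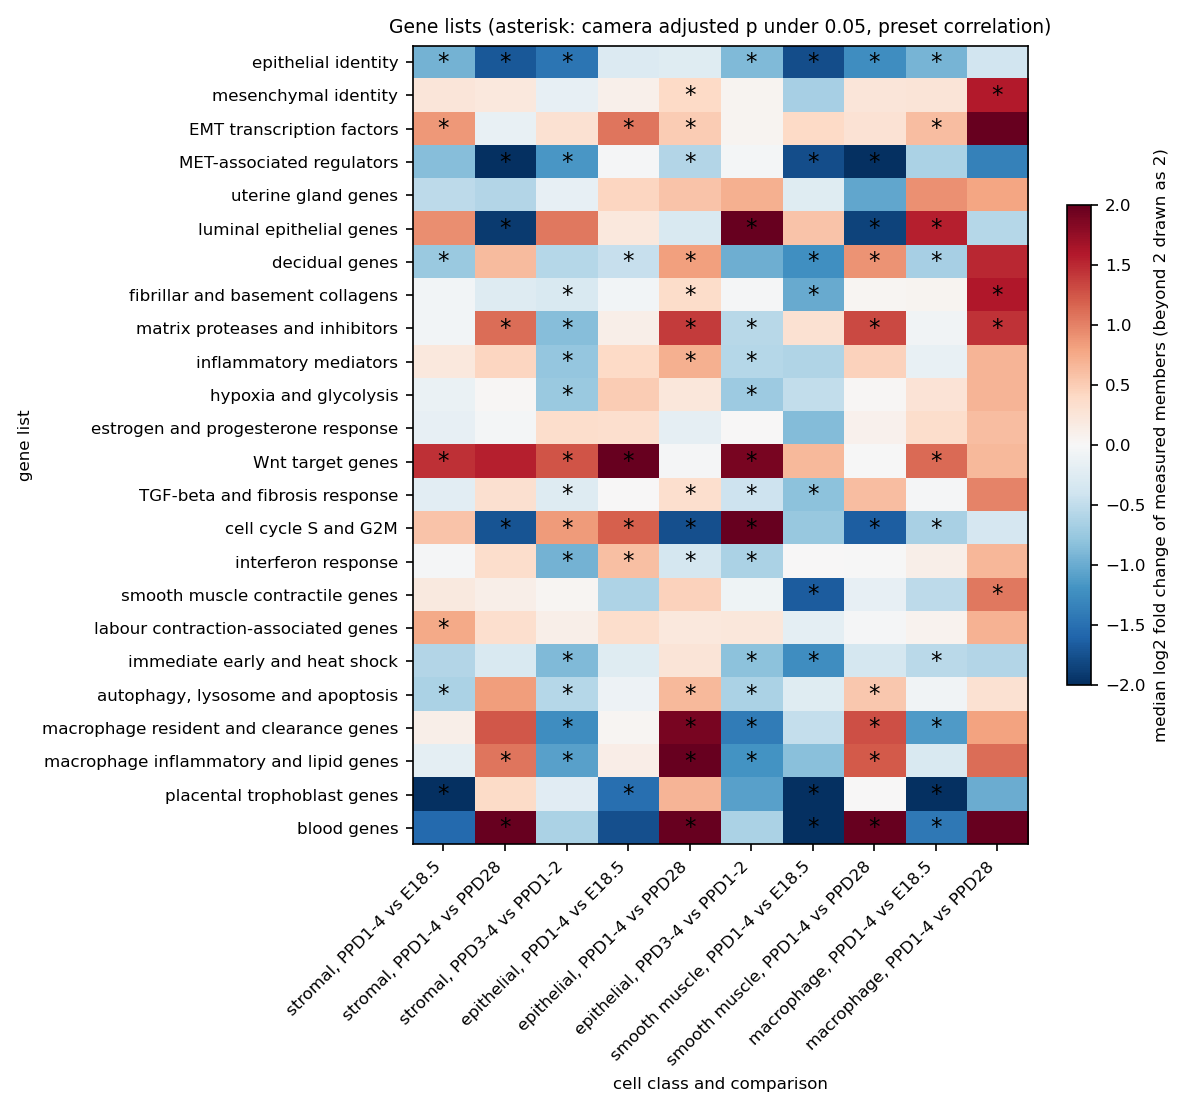
Median log2 change of the measured members of 24 gene lists (y axis) in each cell class and comparison (x axis), with an asterisk where the camera adjusted p is under 0.05. Wnt targets in stroma against E18.5 were at 7.03e-06 (0.185 with an estimated correlation) and contractile genes in smooth muscle at 5.97e-07 (0.241).

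Uterine gland genes and estrogen and progesterone response genes passed in no comparison. Of 17 measured gland genes in epithelium against E18.5, 5 rose and 3 fell (adjusted p = 0.257, 0.814 with an estimated correlation). Of 19 measured estrogen and progesterone response genes in smooth muscle against E18.5, 0 rose and 7 fell (0.104, 0.504 estimated). Median, mean and test differed in sign in 29 of 240 list tests, 0 of them called.

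Genes with a transient course, called in the same direction in PPD1-4 against both E18.5 and PPD28, included in stroma Tnc (5.64 and 4.87), Lef1 (5.37 and 4.63) and Col26a1 (5.45 and 3.87) upward and Col4a4 (-2.32 and -3.45) downward. In epithelium Lef1 (4.89 and 2.76) and Adamts16 rose and Aqp8 (-12.18 and -5.91) fell on both sides. Stroma had 343 genes up and 301 down, with 504 in opposite directions, against 175 and 241 for lists drawn independently. Epithelium had 181 up and 272 down, with 900 in opposite directions, and thus fewer than the 236 and 392 of lists drawn independently. Both comparisons share the PPD1-4 libraries, so those were split, an alternative chosen after the data were seen: with PPD1 and PPD3 against E18.5 and PPD2 and PPD4 against PPD28 there were 282 up and 199 down in stroma, against 93.2 and 119 for lists drawn independently, and 112 and 115 in epithelium, against 107 and 153. The other way round these were 236 and 185, against 181 and 189, and 101 and 97, against 188 and 180. Without PPD28 replicate 1 the counts were 37 and 202 in place of 644 and 453, with Tnc, Lef1 (0.0933) and Col26a1 (0.257) in stroma and Lef1 (0.0603) and Aqp8 (0.623) in epithelium not called against PPD28, and without PPD28 replicate 2, 1186 and 1516. Without E18.5 replicate 1 or 2 they were 313 or 281 and 125 or 94, and in epithelium 184 to 298 without either PPD2 or PPD4 library or PPD3 replicate 2.

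Nuclei that carry transcripts of both stroma and epithelium were counted at 1000 UMIs per nucleus, beside vascular endothelium as a class that should make neither. In stroma, 32.9% and 46.5% of nuclei had at least 2 UMIs of epithelial genes at E18.5, against 53.2% and 68.9% in endothelium, with median depths of 4401 and 5147 UMIs in stroma and 2504 and 2812 in endothelium. At PPD1 the shares were 26.4% and 41.6% (depths of 3238 and 2136), at PPD2 37.5% and 31.6% against 36.8% and 31.2% (2851 and 4234, 2711 and 3642), at PPD3 5.21% and 7.25% against 5.17% and 11.3% (4495 and 4880, 3564 and 3322), and at PPD4 5.47% and 4.18% against 7.77% and 7.01% (3805 and 5866, 2664 and 3830). At PPD28 they were 67.2% and 27.7% against 52.9% and 20.4% (1842 and 2485, 2850 and 2191). The excess of stroma over endothelium averaged -3.33 points ± 5.56 (SD, n = 7) in PPD1-4 and -5.27 ± 18.8 (n = 4) at both ends, a difference of 1.94 (two-sided exact permutation p = 0.812, smallest possible 0.00303), while it varied over times (permutation of F, p = 0.000673, and 0.0677 at 500 UMIs). Mesenchymal transcripts in epithelial nuclei stayed below endothelium in all 11 libraries, by 1.19 to 22.1 points, from 2.51% against 3.70% in PPD28 replicate 2 (depths of 3750 and 2191) to 15.7% against 37.8% in PPD4 replicate 1 (4720 and 2664). That excess was -15 ± 5.39 (n = 7) in PPD1-4 and -5.18 ± 2.99 (n = 4) at both ends, a difference of -9.79 (exact permutation p = 0.0121). Thinning does not equalise RNA from outside the nucleus, as in PPD3 replicate 2, where mesenchymal genes were found in 63.6% of neutrophils (depth of 1320), 37.5% of macrophages (2603), 27.4% of endothelial (3322) and 9.94% of epithelial nuclei (6563). Lower shares than in endothelium therefore do not show that epithelium or stroma lack such nuclei, and the difference of -9.79 may be one of background. It did not pass with at least 3 UMIs (-4.64, permutation p = 0.0606) or with macrophages as background (-9.53, p = 0.10).

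**Figure D4:**
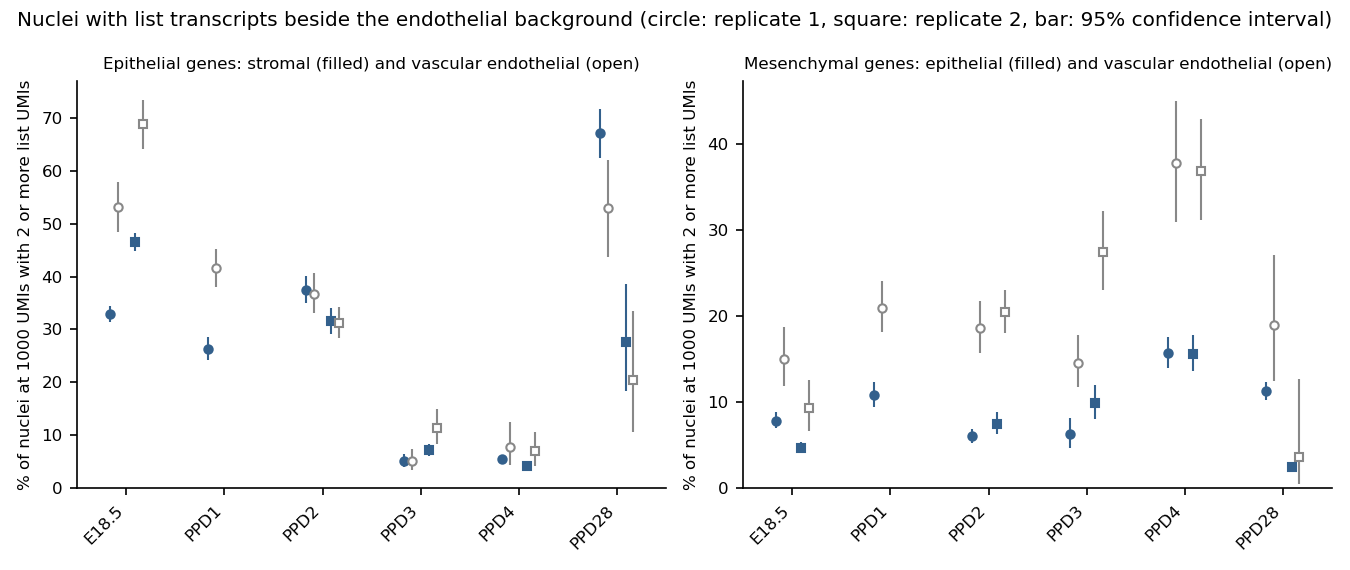
Percent of nuclei at 1000 UMIs with 2 or more list UMIs (y axis) by time point (x axis) for stroma or epithelium (filled) and vascular endothelium (open), with 95% confidence intervals. At PPD3, 5.21% and 7.25% of stromal nuclei held epithelial transcripts, against 5.17% and 11.3% of endothelial nuclei.

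Cycling nuclei, those with at least 3 cell cycle UMIs at 1000 UMIs per nucleus, made up 1.72% (95% confidence interval 1.31 to 2.21) and 2.25% of epithelium at E18.5, 1.66% at PPD1, 1.89% and 4.92% at PPD2, 33.7% (30.4 to 37.1) and 50.6% (47.4 to 53.9) at PPD3, and 7.26% and 24.9% at PPD4. At PPD28 replicate 1 held 55.5% (53.9 to 57.1) and replicate 2 2.75% (2.25 to 3.32). The permutation test of F gave p = 0.272 (adjusted over 8 classes, 0.60), and PPD1-4 against both ends a two-sided p = 0.839 (0.889). Cycling mesothelium averaged 0.928% ± 0.539 (n = 7) in PPD1-4 and 5.37% ± 6.49 (n = 4) at both ends (permutation p = 0.00606, adjusted 0.0485), with 15% in PPD28 replicate 1, without which the difference of -4.44 points was -1.22 (permutation p = 0.0250, unadjusted). Other classes did not pass once adjusted. The stroma of PPD28 replicate 1 held 27.9% cycling nuclei, against 0.625% to 4.18% in the other libraries. That library also held 33.9% in vascular endothelium, 23.2% in lymphatic endothelium, 18.6% in smooth muscle and 17.6% in macrophages, so stroma did not exceed vascular endothelium.

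**Figure D5:**
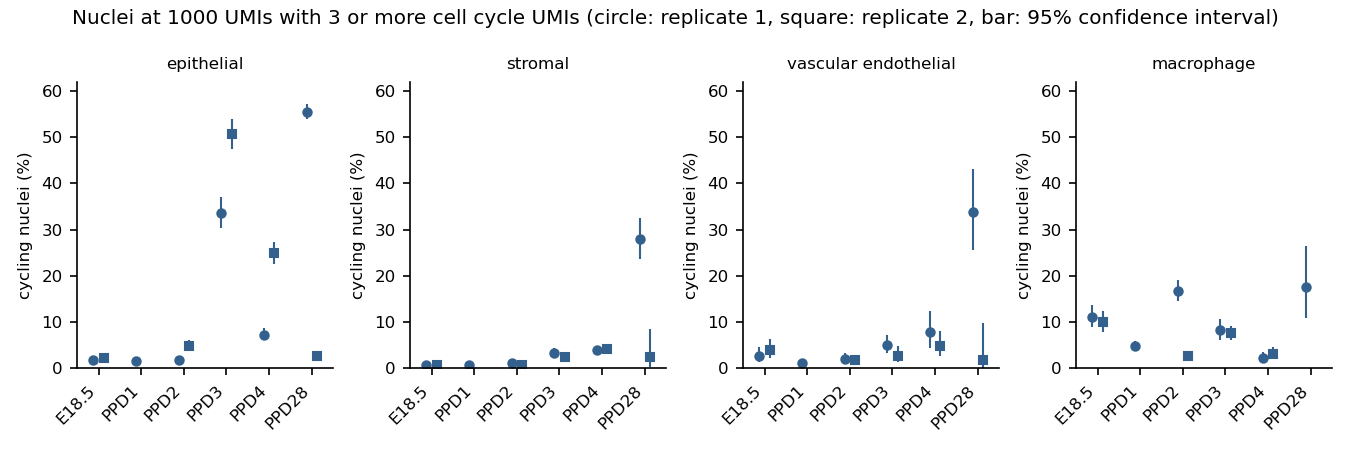
Percent of nuclei with 3 or more cell cycle UMIs at 1000 UMIs (y axis) by time point (x axis) in 4 classes, with 95% confidence intervals. Epithelium reached 33.7% and 50.6% at PPD3, and 55.5% and 2.75% at PPD28.

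The tdTomato transcript, meant to mark cells of the Pdgfra lineage, was found in epithelial nuclei less often than in vascular endothelium, by 4.11 points ± 1.98 (SD, n = 7) in PPD1-4 and by 2.47 ± 3.56 (n = 4) at both ends, a difference of -1.64 (two-sided exact permutation p = 0.336, adjusted over 7 classes 0.906). Stroma stood at -0.125 ± 1.92 (n = 7) and mesothelium at 10.7 ± 9.06 (n = 7) relative to endothelium in PPD1-4, where endothelium itself held 8.69% ± 3.04 (n = 7). No class passed between PPD1-4 and both ends. Stroma, where Pdgfra is made, was above endothelium in 6 of 11 libraries and not on average in PPD1-4, and its CPM lay below that of low-UMI barcodes in each library outside PPD28 (111 against 200 in E18.5 replicate 1 and 185 against 371 at PPD1). The transcript thus cannot show whether epithelial nuclei belong to the lineage.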

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

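The test of depth on cycling nuclei and both tests of other splits of the libraries were chosen after the results were seen.

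Stroma and epithelium changed to a different extent in many genes, tested as the difference itself in a joint fit of 20259 genes. Between E18.5 and PPD1-4 the change differed in 4349 genes, higher in stroma for 1976 and in epithelium for 2373, and 207 were called in opposite directions. Between PPD28 and PPD1-4 it differed in 573, higher in stroma for 185 and in epithelium for 388, with 19 called in opposite directions. Between PPD1-2 and PPD3-4 it differed in 1159, higher in stroma for 556 and in epithelium for 603, with 7 called in opposite directions. Pgr, the progesterone receptor gene, differed by -1.18 between stroma and epithelium against E18.5 (-0.93 and 0.26, adjusted p of the difference 0.0443) and by -1.91 from PPD1-2 to PPD3-4 (0.65 and 2.65, 0.0126). Esr1, the estrogen receptor gene, differed the other way in both, by 0.69 (0.0197) and 0.86 (0.0174). The epithelial junction gene Cdh1 differed by -0.96 against E18.5 (0.0331) and by -1.86 against PPD28 (0.0147). Against PPD28, Grhl2 differed by -2.45 (0.00673), Epcam by -1.95 (0.0321), Zeb2 by -2.19 (0.0181) and Pdgfra by -1.43 (0.0111). Epithelial genes in stroma lay below their low-UMI level, as did Zeb2 (0.143) and Pdgfra (0.144) in PPD1-4 epithelium, so differences in these 5 genes include any change in RNA from other cells. The joint fit was not repeated with libraries left out. In the fit of stroma alone, 135 genes changed against PPD28 without PPD28 replicate 1, in place of 2352, and Epcam stood at 0.40 in place of -1.39, so the differences against PPD28 may rest on that library.

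A small cluster with placental trophoblast and mast cell genes was left unnamed and is in no comparison. It held 311 nuclei in the E18.5 libraries, 108 in replicate 1 and 203 in replicate 2, with 11191 and 18205 trophoblast gene CPM, against 87.3 and 136 CPM in the analysed nuclei of the same libraries.

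The change within the first days was set against other splits of the 7 PPD1-4 libraries, taken as if single libraries were exchangeable. In stroma 1 of 35 splits of these libraries into 4 and 3, the real one, reached its 753 genes, and the highest of the others called 23. In epithelium 1 of 35 splits reached the real 612, and the highest of the others called 0. Most other splits part the libraries of a day, which adds any difference between days to their spread, and 2 keep days whole, too few for a test of days, so that chance between days stays open.

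Falls of Akr1c18, Aqp8, Cuzd1, Guca2b, Prap1 and Rbp4 between E18.5 and PPD1-4 were shared by several classes. Their CPM at E18.5 over the low-UMI CPM had a median of 0.301 in stroma, smooth muscle and macrophages. Rbp4 was highest in stroma (0.869) and the others in epithelium (0.606 to 0.826), so a low ratio leaves RNA from other cells open. The 3 stromal falls named in no other class had a median of 2.72 (Cyp11a1 2.72, Olr1 3.21 and Prl8a2, also open, 0.715). The 6 named stromal rises had a median of 4.15, above what RNA outside nuclei would give. A decline of these transcripts in the cells that make them stays open. Batch was not tested, but dates differ within both sides.

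Macrophages of PPD28 held Timd4, Saa3, Cxcl13, Prg4, Ryr2 and F5 at higher levels than in PPD1-4. Of 9 genes known from macrophages of the peritoneal cavity, 9 were called lower in PPD1-4, among them Tgfb2 (-5.87), Selp (-5.71), Alox15 (-5.27), Garnl3 (-5.25) and Gata6 (-3.39). Endothelial nuclei held at most 0.538% of the macrophage CPM of the first 6 genes, which argues against RNA from other cells. Nuclei of peritoneal macrophages are a candidate source, although Rarb and Tgfb2 were also measured in stroma and smooth muscle. A change of the resident macrophages themselves with time was not tested and stays open.

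Cycling epithelium in PPD28 replicate 1 (55.5%) and not replicate 2 (2.75%) parted the replicates of 1 group. Thinned to 500 UMIs, the shares were 32.9% and 1.13%, 31.7 points apart, which argues against depth. Of the estrogen response genes Ltf, C3, Lcn2 and Muc1, 0 had doubled in replicate 1 (ratios of 0.361, 0.794, 0.400 and 0.921). Other classes had a higher share in replicate 1 too, with 33.9% of vascular and 23.2% of lymphatic endothelium, 18.6% of smooth muscle and 15% of mesothelium, against 1.85%, 1.10%, 1.32% and 1.33% in replicate 2. RNA from other cells was not tested for this pattern and stays open. The estrogen genes argue against an estrogen-dominated stage, but stages are not given in the sources used. A difference between animals may remain, untested.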

How the results depend on the processing

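The alternatives with cluster 12, cluster 16, the first Scrublet run and split libraries were chosen after the data were seen. Of 9387 named gene values under an alternative, 8716 kept their direction and side of the threshold, 565 were no longer called, 88 became called and 18 reversed. Of 4464 list tests these numbers were 4223, 154, 80 and 7, of 645 class share tests 569, 41, 34 and 1, and of 245 tests of nuclei with a transcript 229, 14, 2 and 0. Of 196 counts of changed genes, 149 stayed within 1.5 times, as did 14 of 30 counts of transient genes. The cause was not tested for any change below, apart from the smaller number of libraries where 1 was left out.

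With 1 library left out, changed genes ranged from 2934 to 7860, 135 to 3608 and 808 to 3071 in stroma against E18.5, PPD28 and within PPD1-4, from 2011 to 8048, 1374 to 7000 and 581 to 4067 in epithelium, from 2206 to 5411 and 534 to 3160 in smooth muscle, and from 402 to 2574 and 551 to 2048 in macrophages. Transient genes ranged from 37 to 1186 in stroma and 94 to 1516 in epithelium, and changed class shares from 10 to 24. The difference of nuclei with epithelial genes in stroma ranged from -3.75 to 8.46 points, with mesenchymal genes in epithelium from -10.9 to -8.46, of the tdTomato transcript in epithelium from -3.05 to -0.319, and of cycling nuclei from -3.17 to 15.6 in epithelium and -8.03 to 1.06 in stroma.

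Within the first days, no filter on low counts gave 3076 genes in stroma and 2935 in epithelium, and 2824 in macrophages against E18.5, DESeq2 gave 2968 in epithelium and the first Scrublet run 805. Split libraries gave 421 transient genes in stroma and 227 and 198 in epithelium. Mesenchymal transcripts in epithelium stood at -4.64 points with at least 3 UMIs and -9.53 with macrophages as background. With TMM over classes, smooth muscle share against PPD28 reversed to -0.76. With cluster 12 left out, stromal Col3a1 (-1.29), Zeb1 (-0.23) and interferon genes (adjusted p = 0.00858) reversed against E18.5. At Leiden resolution 0.5, genes changed numbered 224 in stroma against PPD28, 3525 within PPD1-4 and 286 in macrophages against E18.5, with reversals of stromal Epcam (0.71), Klf5 (0.80), Plau (0.048), Ect2 (0.78) and cell cycle genes (adjusted p = 0.0747) and macrophage Mrc1 (0.53), Anln (2.19), Lyve1 (1.89), Cd163 (1.03), Alas2 (0.22) and cell cycle genes (adjusted p = 0.991). With 1 library left out, stromal genes against PPD28 ranged from -1.94 to 0.40 for Epcam, -2.40 to 0.63 for Klf5 and -3.25 to 0.75 for Ect2. Epithelial genes against PPD28 ranged from -1.33 to 2.67 for Col1a1, -1.95 to 3.72 for Mki67, -2.62 to 0.25 for Hmgb2 and -3.64 to 1.39 for Anln. The higher value of each was without PPD28 replicate 1 and the lower without replicate 2. Cell cycle genes against PPD28 reversed without PPD28 replicate 1, at adjusted p = 0.0826 in stroma, 2.30e-07 in epithelium and 0.349 in smooth muscle, and ranged from 2.90e-15, 1.09e-15 and 9.63e-13 without replicate 2 to 0.0826, 0.232 and 0.349. Epithelial collagens against PPD28 reversed without replicate 2 (0.965) and were at 3.29e-07 without replicate 1.

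With the replicate number as a block, the counts were 6192, 2053 and 1657 in stroma, 5456, 3678 and 1306 in epithelium, 4683 and 2539 in smooth muscle, and 2243 and 2051 in macrophages, although correlations of replicate numbers across times, from -0.135 to 0.188 and highest between PPD2 and PPD4, do not show that numbers pair the libraries. Depth limits the stroma of PPD28, with 405 and 83 nuclei of at least 1000 UMIs, and the macrophages there, with 102 and 38.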

Other observations

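The transient genes below were chosen after their values were seen. Stromal Sptlc3, for an enzyme of sphingolipid synthesis, rose in PPD1-4 by 4.91 against E18.5 and 4.58 against PPD28, and Rarb, for a retinoic acid receptor, by 3.35 and 3.83. The R-spondin receptor gene Lgr6 fell in stroma by 4.42 and 6.12. In epithelium the collagen gene Col8a1 rose by 3.34 and 2.77, the secretin receptor gene Sctr fell by 4.39 and 3.23, and the ion channel gene Asic2 by 3.68 and 2.90. None kept its call against PPD28 without PPD28 replicate 1 (adjusted p = 0.341, 0.171, 0.661, 0.0505, 0.175 and 0.170), where Lgr6 stood at 7.33.

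Unnamed clusters held 4245 nuclei, mostly cluster 16, and doublet clusters 4201.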
